A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

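RNA was sequenced from budding yeast (Saccharomyces cerevisiae), namely a wild-type that the series record calls diploid while its label gives BY4741, and 4 heterozygous strains in which 1 copy of a chromosome I gene was replaced. Per the labels, cells grew in YPD, a rich medium with glucose, at 30 °C in log phase, from an optical density of 0.2 to 1.0, without the drug G418. The labels' protocols describe RNA extraction with Trizol and a column, 2 rounds of poly-A selection on oligo-dT beads, fragmentation to an average of 200 to 300 bases, adapter ligation, amplification and size selection. The labels give no sequencing date or batch, and they do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

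The authors deposited 1 table of estimated counts for 6606 open reading frames (ORFs) in 18 libraries, and every column of values was used. Per the submitters' processing notes, Bowtie 0.12.5 was among the tools. The genome build, the annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here. The name of the deposited table says that counts cover the last 200 bases of each ORF. Of the 118908 values, 93.0% were whole and 6.98% were multiples of 0.5 that are not whole. No value exceeded 201, and the spread between libraries shrank as values neared that ceiling, so the values behave like a number of distinct read positions in a window of 201 bases. Strong genes are therefore compressed: a fold change near the ceiling understates the change. In 13 pairs of ORFs on opposite strands whose windows overlapped by at least 180 bases, the summed counts differed by a median of 0.04 on the log2 scale. Reads of overlapping antisense ORFs can then not be told apart. Near-identical paralogs may also share counts. The affected genes named here are ICS2, which overlaps another ORF, STE2, HXT6 with HXT7, RME1, SSA1 with YAL004W, and MTW1 with YAL034C-B.

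Symbols came from the RefSeq table of assembly R64, which paired 5918 ORFs by systematic name and left 688 unpaired under their systematic names. Only 896 of the paired ORFs had the start and end that R64 gives. Coordinates printed here are therefore those of the deposited table, in a build not given in the sources used here. R64 sequence was used only for the GC content of the last 200 bases, which was known for 91.2% of the 2856 tested ORFs.

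Wild-type replicates 1 and 2 were compared by a chi-square test under an occupancy model with 202 positions, over ORFs with a mean count from 8 to 120. They differed by less than the sampling noise and were averaged into 1 library. Wild-type then had n = 5, and 17 libraries entered the fit. The exact permutation tests of 3 against 5 libraries have 56 splits, so they differ from the splits of 3 against 6 that had been planned.

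Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean (TMM) factors, filterByExpr by group with a minimum count of 10, and the quasi-likelihood test with a mean per group. All groups entered 1 fit and shared 1 estimate of the spread, since each strain had 3 libraries. The contrasts were each strain minus wild-type, the mean of the 4 strains minus wild-type, and an F test among the 4 strains. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts per 1e6 of the TMM-scaled library size and are given as mean ± SD. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over 20 lists within a comparison. Of the 25 lists fixed, 5 had fewer than 3 tested members and were not run: meiosis and sporulation, auxotrophic markers, nitrogen catabolite genes, subtelomeric families and mitochondrially encoded genes. Neighbours of a replaced gene were tested ORFs whose systematic number lay within 5 of it. Their median absolute log2 fold change was set against all runs of as many tested ORFs in systematic order on any arm.

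The genes named in the text followed a rule: the 4 replaced genes, their nearest tested neighbours, up to 10 rising and 10 falling genes per comparison among those past the threshold with every library of the strain on the same side of the wild-type mean, up to 4 members per list past its threshold with the smallest p, the 10 smallest p of the F test, the auxotrophic markers, and 4 mating genes. GIP4 and SEO1 did not pass the count filter. GIP4 was tested in the fit without the filter, and SEO1 is given by counts. The design, the gene lists, this rule and the first set of alternatives were fixed before the data were examined. The mating genes grouped as a-specific, haploid-specific and alpha-specific come from the fixed mating list. IME4, TEC1, DDR2 in the FUN14 heterozygote and EFB1 were named after their values were seen. The values of 1 called gene are not reported here.

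Total counts ran from 52294 to 132618 per library with a median of 98166. By these totals, without TMM scaling, a single count was therefore worth 7.54 to 19.1 CPM, and most ORFs were too thinly covered for small changes. On the TMM-scaled sizes its worth could be higher: 2 GIP4 counts in replicate 3 of the FUN26 heterozygote gave 43.5 CPM. The test was run on simulated data for the comparison of 3 strain libraries with 5 wild-type libraries over 2856 genes. It called 3% of genes changed 1.5-fold, 17.4% of those changed 2-fold, 78.4% of those changed 4-fold and 94.6% of those changed 8-fold, and 3.3% of the calls were false. The mean of the 4 strains called 50.3% of genes changed 2-fold, and the F test called 14.7%, in simulations of those comparisons. The simulated genes varied independently, whereas in the data many genes moved together between libraries. Regrouped real libraries called up to 859 genes, so these rates of power and of false calls need not hold for the data. Counting intervals are exact binomial intervals at 95%, and a floor of 3 counts over the group stands for a count of 0. Both cover counting error only.

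Alternatives tried before the data were examined were DESeq2 1.42.0, RLE, upper-quartile and total-count scaling, no count filter or a mean of at least 10 CPM, glmTreat against a 1.2-fold change, only the groups compared, 3 wild-type replicates at a time, the replicate number as a block, library sizes without chromosome I and the 20 strongest genes, neighbour windows of 3 and 10, and leaving out each library. Alternatives chosen after seeing the data were wild-type replicates 1 and 2 as separate libraries, occupancy-corrected counts, no wild-type libraries 3 and 5, a GC correction per library, 1 surrogate variable from sva 3.50.0, and the other 3 strains as reference. In the setting with wild-type replicates 1 to 3, replicates 1 and 2 stayed averaged, so wild-type had n = 2 there. The replicate block was fitted with replicates 1 and 2 as separate libraries. The table as analysed has no row for the replacement cassette, whose expression was not analysed here.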

Results

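The study concerned how the position of a gene on a chromosome bears on expression. The data describe poly-A RNA from budding yeast growing in rich glucose medium. The 4 strains were heterozygous diploids from a replacement series, each with 1 of the 2 copies of a chromosome I ORF replaced: SEO1 (YAL067C, a putative permease), GIP4 (YAL031C, a protein linked to the type 1 phosphatase Glc7), FUN26 (YAL022C, a vacuolar nucleoside transporter) and FUN14 (YAL008W, a mitochondrial membrane protein). Each strain had 3 libraries, and the wild-type, described as diploid in the series record, had 6. The label of every library gives BY4741, a haploid a-mating-type strain, as the background, while the deposited columns of the wild-type carry the name of the diploid BY4743. Total counts ran from 66764.5 to 116519.5 in wild-type, 69626.5 to 132618 in the SEO1 heterozygote, 66145 to 126675.5 in the GIP4 heterozygote, 52293.5 to 111600.5 in the FUN26 heterozygote and 72922 to 99458.5 in the FUN14 heterozygote.

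Wild-type replicates 1 and 2 differed by less than the sampling noise, with a chi-square per ORF of 0.970 over 2513 ORFs (p = 0.858), and were counted as 1 sample. The 14 other wild-type pairs ranged from 2.07 to 9.84 on the same measure, and the 126 pairs from different groups from 1.35 to 12.8. The remaining 17 libraries did not line up by group: the first principal component held 44.8% of the variance of log2 CPM, and 36.5% of its scores' variance lay between groups. Mean scores were −5.68 ± 26.0 in wild-type (n = 5), 8.53 ± 28.3 in the SEO1 heterozygote, −20.4 ± 14.9 in the GIP4 heterozygote, −0.22 ± 13.8 in the FUN26 heterozygote and 21.5 ± 7.59 in the FUN14 heterozygote (SD, n = 3 each). The ribosome biogenesis genes followed this axis, with a median correlation of 0.60 over the libraries, and the cytosolic ribosomal protein genes did so with 0.37. These are medians across genes within lists, which are not independent replicates.

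**Figure D1:**
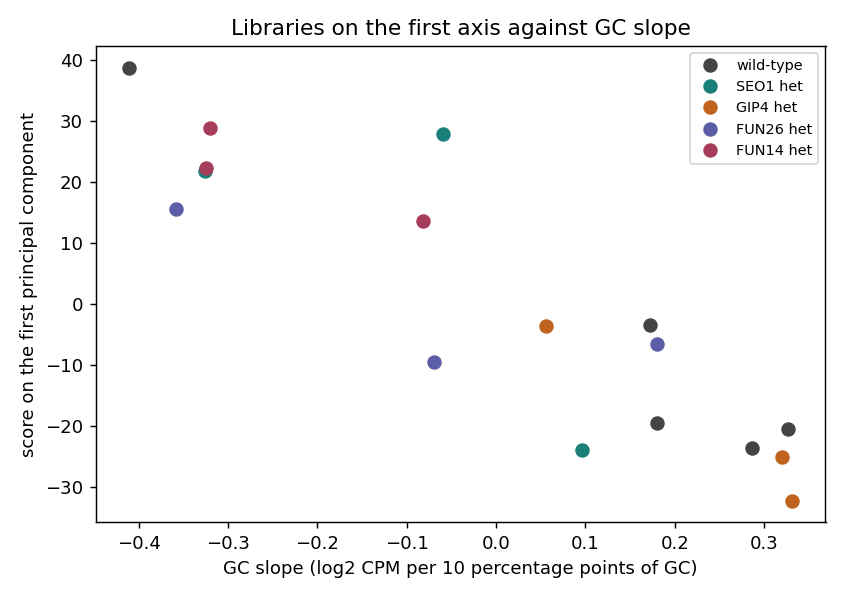
Score of each of the 17 libraries on the first principal component of log2 CPM against its GC slope (log2 CPM per 10 percentage points of GC in the counted window), coloured by group. The libraries of a group are spread along the axis, and wild-type library 3, at a slope of −0.41, lies apart from the other wild-type libraries.

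The replaced genes were examined first, since a heterozygote should carry a single intact copy. GIP4, FUN26 and FUN14 were each lower in their own strain than in wild-type, and each was also lower there than in the other strains. FUN14 (chromosome 1, 136916 to 137512) stood at 164 ± 28.7 CPM in its own strain (n = 3), 309 ± 51.2 in wild-type (n = 5) and 285 ± 35.1 in the 9 libraries of the other strains. FUN26 (chromosome 1, 108878 to 110431) stood at 136 ± 65.0 CPM in its own strain, 269 ± 117 in wild-type and 264 ± 94.5 in the other strains. GIP4 (chromosome 1, 84750 to 87032) stood at 9.79 ± 9.02 CPM in its own strain, 57.0 ± 22.7 in wild-type and 54.0 ± 17.6 in the other strains. The own-strain libraries held 3 GIP4 counts in all, so wild-type exceeded them by a ratio of 4.76 with a counting interval of 1.44 to 24.8.

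By edgeR's quasi-likelihood test against wild-type, FUN14 fell by 0.90 ± 0.27 on the log2 scale (SE), FUN26 by 0.95 ± 0.45 and GIP4 by 2.07 ± 0.62. Adjusted over the list alone, these 3 genes, edgeR's p was 0.00501 for GIP4, 0.0460 for FUN26 and 0.00501 for FUN14. Adjusted over all genes none of these passed the threshold, with values of 0.149, 0.980 and 0.612 for FUN14, FUN26 and GIP4. Exact two-sided permutation tests on log2 CPM gave p = 0.0179 for FUN14 and for GIP4, the smallest that 56 splits allow, and p = 0.125 for FUN26. Against the other strains the exact p was 0.00455, 0.0227 and 0.00455 for FUN14, FUN26 and GIP4, where 0.00455 is the smallest that 220 splits allow. The FUN26 difference was narrow: beside the exact p of 0.125, DESeq2 gave p = 0.0503, and without own replicate 1 the log2 difference was −0.68 with an edgeR p of 0.198. It also missed 0.05 without wild-type replicates 2, 4 or 6 (−0.89, −0.76 and −0.88), SEO1 replicate 3 (−0.92), GIP4 replicate 3 (−0.95), own replicate 3 (−0.84) or FUN14 replicates 1, 2 or 3 (−0.95 each). SEO1 (chromosome 1, 7236 to 9017) had 4 counts in all 18 libraries, all in wild-type, and 0 in its own strain, where the floor of 3 counts is 10.8 CPM, so a loss was not detectable at this depth.

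**Figure D2:**
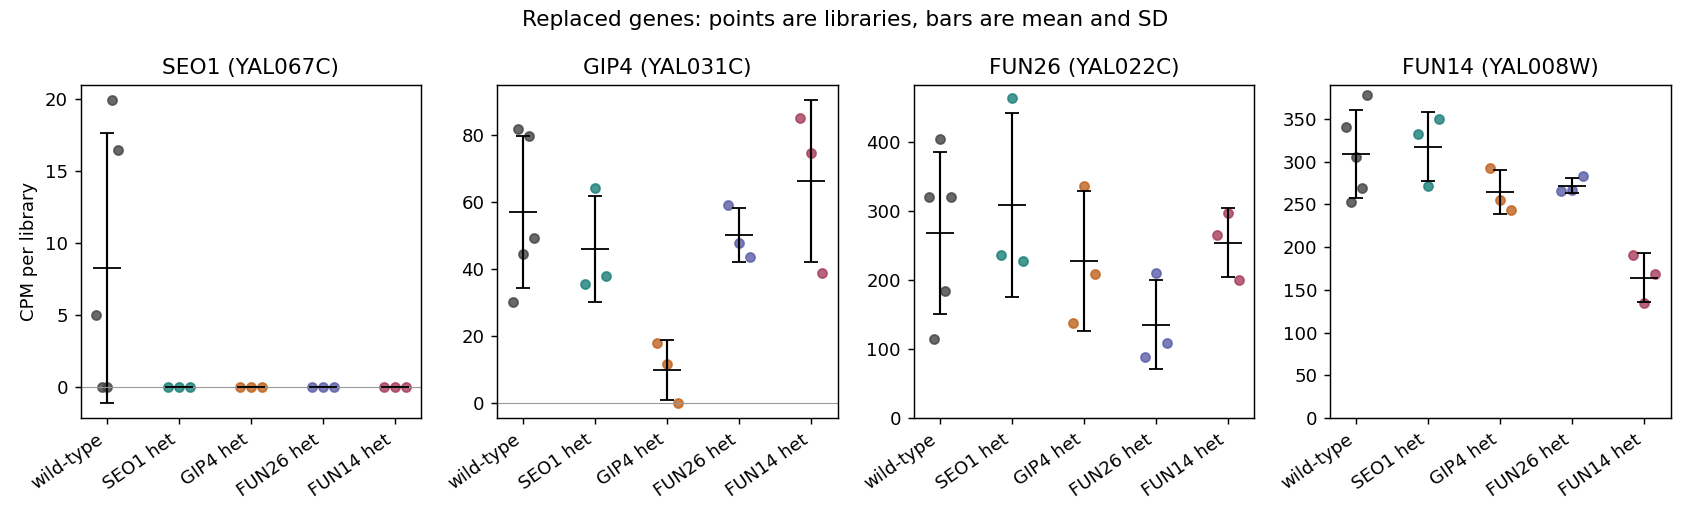
CPM of the 4 replaced genes per library (points) with mean and SD (bars) in wild-type and the 4 heterozygotes. GIP4, FUN26 and FUN14 have their lowest group mean in the strain that carries the replacement, at 9.79, 136 and 164 CPM.

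The comparison of all replacement strains with wild-type asks what the strains had in common wherever the replacement sat. It cannot tell an effect of carrying a replacement from a difference of the cells labelled wild-type, which every strain comparison shares. Genes of the mating response and of haploid cell identity were on average far lower in the 12 strain libraries than in the 5 wild-type libraries. STE2, the alpha-factor receptor, stood at 11.7 ± 12.2 CPM in the strains and 334 ± 119 CPM in wild-type, with 10 against 135 summed counts, a ratio of 33.6 (counting interval 17.7 to 71.6). MFA2 and MFA1, which encode the a-factor pheromone, were lower by ratios of 41.0 (21.8 to 87.2) and 19.9 (9.05 to 51.7). FUS3, the kinase of the pheromone pathway, was lower by 33.6 (20.8 to 57.6), and FAR1, which arrests the cell cycle in response to pheromone, by 10.6 (6.06 to 19.5). The G protein subunits STE18 and STE4 were lower by 8.29 (5.20 to 13.7) and 5.47 (3.50 to 8.73).

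Single libraries departed from this: in wild-type replicate 3 FUS3 stood at 49.0 CPM, against 557 to 870 in the other wild-type libraries and 44.4 in GIP4 replicate 1, and STE4 at 49.0, below FUN26 replicate 3 at 65.2. With wild-type replicates 1 to 3 alone FUS3 fell below the count filter.

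In the edgeR fit 11 of 2856 tested genes changed, 1 higher and 10 lower, with adjusted p from 1.00e-08 for MFA2 to 0.0239 for TEC1. The other lower genes were ICS2, of no known function, by a ratio of 7.87 (5.18 to 12.3), HXT6, a high-affinity glucose transporter nearly identical to HXT7, by 6.27 (3.89 to 10.4), and TEC1, a transcription factor of filamentous growth, by 3.26 (2.52 to 4.21). TEC1 stood at 216 ± 53.0 CPM in the GIP4 heterozygote and 26.3 ± 16.5 in the FUN14 heterozygote (adjusted p = 0.463 in the edgeR F test among strains), and in wild-type replicate 3 it stood at 32.7 CPM against 294 to 556 in the other wild-type libraries. The TEC1 call ended, at adjusted p from 0.0506 to 0.118, without wild-type replicates 4, 5 or 6, GIP4 replicate 2 or FUN14 replicates 1 or 3. HXT6 fell below the filter without wild-type replicates 3, 4 or 5, and STE4 without 5 or 6. For HXT7, the near-identical paralog of HXT6, the libraries overlapped, at 32.7 to 318 CPM in wild-type and 14.9 to 331 in the strains. All 7 tested members of the fixed mating list fell, both over all genes and adjusted over the list alone, and DESeq2 called 17 genes, 2 higher and 15 lower, among them the 11 that edgeR called. The count moved to 22 genes without the count filter, with 2 higher and 20 lower, and with wild-type replicates 1 to 3 alone it was 11, with 4 higher and 7 lower.

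Most of the mating list lay below the count filter, so its 21 members were also summed by class. The 6 a-specific genes together stood at 1222 ± 249 CPM in wild-type and 83.5 ± 50.5 in the strains, and all 6 were higher in wild-type. The 11 haploid-specific genes stood at 1416 ± 222 and 143 ± 58.0 CPM, and all 11 were higher in wild-type. The lowest wild-type library was at 955 CPM for the a-specific genes and the highest strain library at 174. Both classes gave an exact permutation p of 0.000162, the smallest that 6188 splits allow. The 4 alpha-specific genes stood at 82.5 ± 56.6 and 69.4 ± 36.1 CPM (exact permutation p = 0.570). Among them the alpha-factor gene MF(ALPHA)1 had 4 counts in wild-type and 16 in the strains, and STE3, the a-factor receptor, had 2 and 1.

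**Figure D3:**
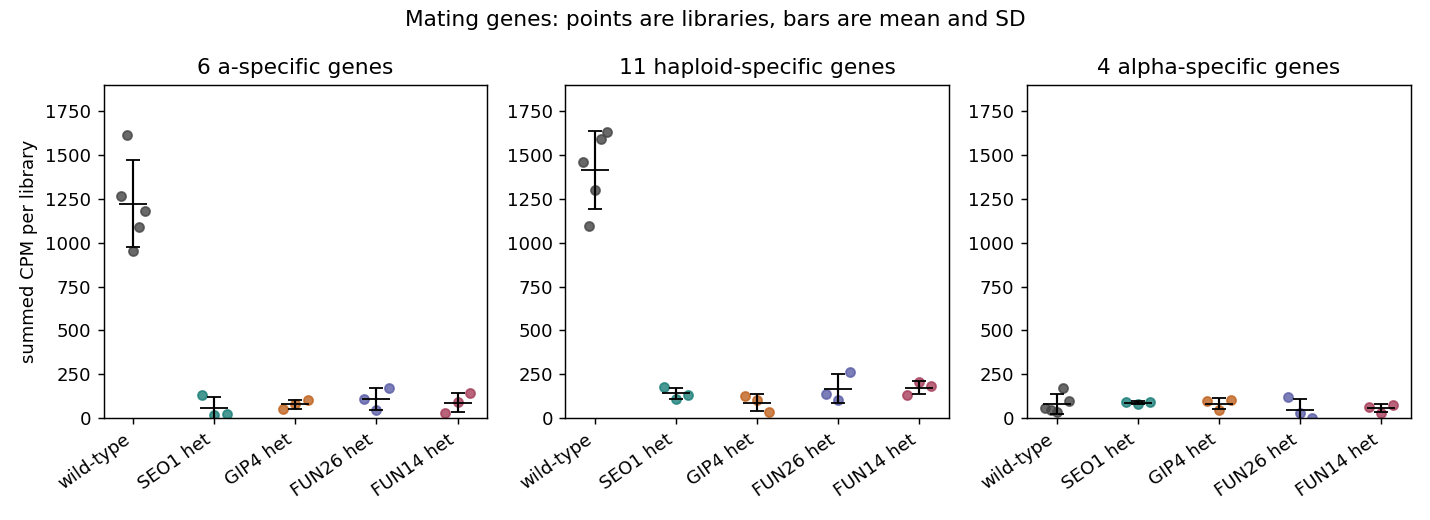
Summed CPM per library (points, with mean and SD as bars) of the 6 a-specific, 11 haploid-specific and 4 alpha-specific genes of the mating list in wild-type and the 4 heterozygotes. Wild-type libraries lie at 955 CPM or above for the a-specific genes, strain libraries at 174 or below, and the alpha-specific genes are low in every group.

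Amino acid biosynthesis genes under the activator Gcn4 were higher in the strains. The list of 30 tested genes had a median log2 fold change of 0.51 in the mean of the strains, 29 of the 30 were positive, and camera gave an adjusted p of 5.05e-15, or adjusted p = 0.000171 with an estimated correlation. Over all genes 1 member passed the threshold, and adjusted over the list alone 8 did. HIS4 of histidine synthesis stood at 173 ± 105 against 54.3 ± 14.2 CPM in wild-type, HIS5 at 176 ± 46.2 against 94.3 ± 30.0, and LYS1 of lysine synthesis at 335 ± 69.2 against 192 ± 36.1. In each strain taken alone the list was higher too, with median log2 fold changes of 0.45, 0.54, 0.50 and 0.58 in the SEO1, GIP4, FUN26 and FUN14 heterozygotes and estimated-correlation adjusted p of 0.00246, 0.00127, 0.00174 and 0.00755. These comparisons share their wild-type libraries and are not independent of each other.

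**Figure D4:**
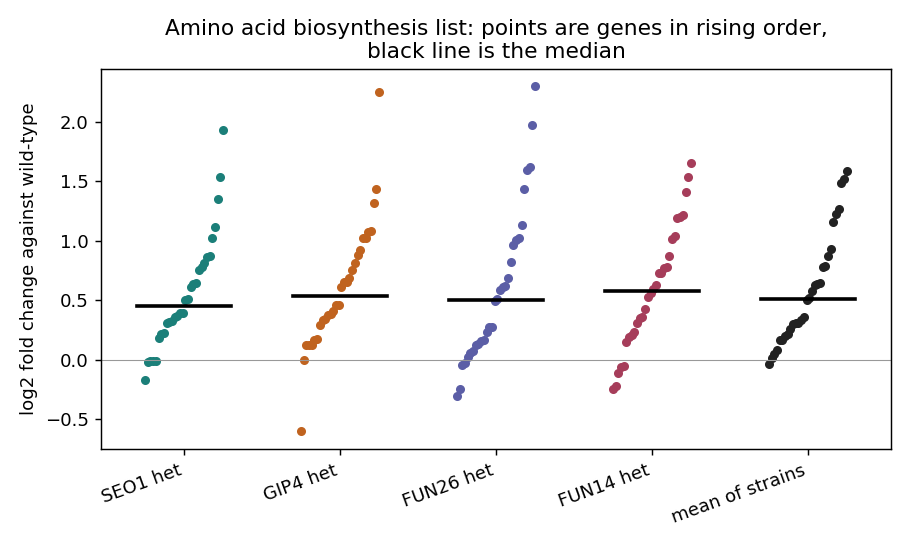
Log2 fold change against wild-type of the 30 tested amino acid biosynthesis genes (points, in rising order) in each heterozygote and in the mean of the strains, with the median as a black line. The medians lie between 0.45 and 0.58.

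Several broader lists were higher in the mean of the strains by smaller amounts. The nucleotide synthesis list had a median log2 fold change of 0.26 over 21 genes (camera adjusted p = 0.00923) and the phosphate list 0.29 over 12 genes (0.00923); for both, adjusted p = 0.0429 with an estimated correlation. With wild-type replicates 1 to 3 alone neither passed, at adjusted p = 0.188 and 0.350. ADE2 of purine synthesis stood at 309 ± 62.2 against 178 ± 105 CPM, URA1 of pyrimidine synthesis at 589 ± 105 against 409 ± 138 and the vacuolar phosphatase gene PHO8 at 525 ± 108 against 351 ± 129, and none of these passed the threshold alone. The general stress list had a median of 0.36 over 31 genes, with adjusted p = 0.169 with an estimated correlation. Of its members 25 were positive and none passed the threshold alone: SSA4 and HSP104 stood at 1352.5 ± 428 and 662 ± 166 CPM against 864 ± 344 and 432 ± 186 in wild-type, while DDR2 stood at 87.8 ± 85.0 against 223 ± 163. The ribosome biogenesis list had a median of 0.16, with adjusted p = 0.574 with an estimated correlation, and it is among the lists that follow the library axis.

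Each strain was then set against wild-type to ask in which genes it differed. The same wild-type libraries served each time. A difference from wild-type alone can therefore not be assigned to the replaced locus rather than to the cells labelled wild-type. In the SEO1 heterozygote 4 genes changed in the edgeR fit, all lower: MFA2 (2 counts against 165, ratio 55.7, counting interval 15.2 to 464), STE2 (1 against 135, 91.2, 16.1 to 3628), FUS3 (4 against 243, 41.0, 15.8 to 152) and STE18 (9 against 80, 6.00, 3.01 to 13.6). HIS4 stood at 212 ± 150 against 54.3 ± 14.2 CPM (adjusted p = 0.130). The ribosome biogenesis list was higher by a median of 0.33 (23 of 29 genes positive), the phosphate list by 0.22 and the stress list by 0.29, with adjusted p = 0.390, 0.113 and 0.560 with an estimated correlation. RRP5, a factor of small-subunit assembly, stood at 248 ± 50.3 against 134 ± 30.4 CPM. The STE18 call ended, at adjusted p from 0.0647 to 0.286, without wild-type replicates 1, 3, 4, 5 or 6 or own replicates 2 or 3, and DESeq2 did not make it; the FUS3 call ended without own replicates 2 or 3 (0.0790 to 0.146). The count of 4 became 114 without own replicate 1, 2 without own replicate 2, 2 without own replicate 3 and 7 without FUN14 replicate 2, and it was 8 without the count filter.

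In the GIP4 heterozygote 8 genes changed, 7 lower and 1 higher. The lower genes were MFA2 (3 counts against 165, ratio 34.2, counting interval 11.5 to 167), STE2 (4 against 135, 21.0), FUS3 (6 against 243, 25.2, 11.4 to 69.2), STE18 (3 against 80, 16.6, 5.47 to 82.0), FAR1 (1 against 68, 42.2, 7.33 to 1693), ICS2 (4 against 95, 14.8, 5.58 to 55.3) and MFA1, which had 0 counts and was at least 11.6-fold lower against a floor of 3 counts over the group. HIS4 rose from 54.3 to 262 CPM (log2 fold change 2.25 ± 0.45, edgeR adjusted p = 0.0284), a call that ended, at adjusted p from 0.0566 to 0.390, without wild-type replicates 1, 3, 4, 5 or 6 or own replicates 1 or 3. Of the amino acid list 6 members rose adjusted over the list alone. The stress list was higher by a median of 0.37 (27 of 31 genes positive), the glycolysis list by 0.19 with all 16 genes positive, and the list of outermost ORFs on each arm by 0.28, with adjusted p = 0.216, 0.402 and 0.0872 with an estimated correlation. Among these, SOL4 of the stress list stood at 322 ± 375 against 78.1 ± 18.2 CPM and ENO1, an enolase, at 426 ± 198 against 297 ± 65.8. The count of 8 became 4, 5 and 5 without own replicates 1, 2 and 3, which between them ended the calls of MFA1, FAR1, FUS3 and ICS2 at adjusted p from 0.0556 to 0.131.

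In the FUN26 heterozygote 6 genes changed, 5 lower and 1 higher. MFA2 (2 counts against 165, ratio 50.5, counting interval 13.7 to 420), STE2 (3 against 135, 27.5, 9.22 to 135), FUS3 (6 against 243, 24.8, 11.2 to 68.2), STE18 (4 against 80, 12.2, 4.59 to 46.0) and FAR1 (2 against 68, 20.8, 5.54 to 175) were lower. Of the amino acid list 6 members rose adjusted over the list alone. FUN26 transports nucleosides, and the nucleotide synthesis and salvage list was higher by a median of 0.21 (16 of 21 genes positive, adjusted p = 0.0421 with an estimated correlation), with ADE13 at 893 ± 162 against 582 ± 108 CPM and ADE17 at 312 ± 145 against 166 ± 46.9. Against the other 3 strains this list had a median of 0.10 and an adjusted p of 0.654, so a difference specific to this strain was not shown. With wild-type replicates 1 to 3 alone the list's adjusted p against wild-type was 0.112. The respiratory chain list was higher by 0.20, the stress list by 0.30 and the phosphate list by 0.28, with adjusted p = 0.266, 0.266 and 0.0758 with an estimated correlation. The count of 6 became 1, 3 and 3 without own replicates 1, 2 and 3 and 3 without wild-type replicate 4. The FAR1 call ended without any of wild-type replicates 1, 3, 4, 5 and 6 or of the own replicates (adjusted p from 0.0545 to 0.283), FUS3 without wild-type replicates 4 or 6 or any own replicate (0.0522 to 0.283), and STE18 and STE2 without own replicate 1 (0.0643).

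In the FUN14 heterozygote 9 genes changed, 7 lower and 2 higher. An unadjusted p under 0.05 in edgeR was reached by 477 genes, against 112, 138 and 124 in the SEO1, GIP4 and FUN26 heterozygotes. Chance gives 142.8 on average, but the library axis moved many genes together, so a count can lie far from that by chance. MFA2 (3 counts against 165, ratio 31.8, counting interval 10.7 to 156), STE2 (2 against 135, 39.0, 10.6 to 326), FUS3 (2 against 243, 70.3, 19.2 to 584), STE18 (8 against 80, 5.78, 2.80 to 13.9), ICS2 (4 against 95, 13.7, 5.19 to 51.5), HXT6 (1 against 63, 36.4, 6.31 to 1462) and TEC1 (6 against 144, 13.9, 6.22 to 38.5) were lower. APJ1, a J-domain co-chaperone, rose from 65.1 ± 34.0 to 291 ± 78.3 CPM (edgeR adjusted p = 0.0343). Of the stress list, adjusted over the list alone, 4 chaperone genes rose and 1 gene fell: HSP78 stood at 551 ± 72.5 against 192 ± 89.2 CPM, HSP42 at 852 ± 82.5 against 305 ± 149, SSA4 at 1891 ± 243 against 864 ± 344, HSP104 at 872 ± 96.6 against 432 ± 186, and DDR2 at 25.6 ± 4.29 against 223 ± 163. The stress list as a whole had a median of 0.20, with adjusted p = 0.446 with an estimated correlation. The ribosome biogenesis list was higher by 0.47 (25 of 29 genes positive) and the cytosolic ribosomal protein list by 0.13 (85 of 130), with adjusted p = 0.299 and 0.884 with an estimated correlation, and all 3 libraries of this strain lay on the positive side of the library axis, at 13.6 to 28.8. The count of 9 became 175 without wild-type replicate 3, 4 and 3 without wild-type replicates 4 and 5, 114 and 14 without SEO1 replicates 1 and 3, and 2, 3 and 2 without own replicates 1, 2 and 3, and DESeq2 called 34 genes, 10 higher and 24 lower. Without 1 own replicate the calls of APJ1, TEC1, STE18, ICS2 and FUS3 ended in all 3 cases and that of HXT6 in 2. The APJ1 call also ended without wild-type replicates 1, 5 or 6, GIP4 replicate 2 or FUN26 replicate 1 (adjusted p from 0.0506 to 0.252), and TEC1 without wild-type replicates 1, 4, 5 or 6, SEO1 replicate 2, GIP4 replicates 2 or 3 or FUN26 replicate 1 (0.0567 to 0.380). STE18 also ended without wild-type replicates 1, 4 or 5 (0.0590 to 0.196) and ICS2 without 4 or 5 (0.0523 to 0.166), and HXT6 fell below the filter without 3, 4 or 5.

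Over the 4 strains 12 genes were called in at least 1 strain, and 6 of them belong to the mating list. FUS3, STE2, STE18 and MFA2 were called lower in all 4 strains in the edgeR fit. Of these, MFA2 kept its call in each strain under all 35 alternatives, while STE18 in the SEO1 heterozygote kept it in 20 of 35. Each pair of strains shared 4 or 5 lower genes, where independent lists of these sizes would share 0.00700 to 0.0172, and unchanged groups simulated against the same wild-type libraries shared 0, with 0.0750 calls per group on average, so that few could be shared. With the wild-type libraries split so that each strain met different controls, pairs still shared 2.40 to 3.45 lower genes on average. All of these controls still came from the libraries labelled wild-type. The fold changes of all genes correlated between strains from −0.11 to 0.72 across genes, against 0.37 to 0.38 in unchanged groups with shared controls, and the covariance minus its simulated value ran from −0.10 to 0.15.

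Differences among the strains bear on the question whether the position replaced matters for the rest of the genome. No gene differed among the 4 strains in the edgeR F test, where 287 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.463. DESeq2 called 2 genes. The genes with the smallest p included IGD1, a regulator of glycogen debranching, at 434 ± 220, 913 ± 122, 597 ± 185 and 107 ± 37.1 CPM in the SEO1, GIP4, FUN26 and FUN14 heterozygotes, CUE5, an autophagy receptor, at 296 ± 281, 768 ± 21.0, 504 ± 68.4 and 118 ± 21.4, and APJ1 at 81.4 ± 40.3, 82.5 ± 38.7, 66.2 ± 19.7 and 291 ± 78.3. GPD1 of glycerol synthesis followed the order of IGD1, at 367 ± 246, 984 ± 22.0, 728 ± 159 and 257 ± 101 CPM. For IGD1, CUE5 and GPD1 the order of the strains was the reverse of their mean scores on the library axis, and in wild-type replicate 3, the highest on that axis, IGD1 stood at 81.7 CPM against 604 to 952 in the other wild-type libraries. In the 6 edgeR contrasts between pairs of strains 0 genes passed the threshold, with 58 to 646 genes at an unadjusted p under 0.05, the most between the GIP4 and FUN14 heterozygotes; DESeq2 was not run on these pairs. The F test result rested on SEO1 replicate 1, without which 217 genes passed, and became 1 gene without wild-type replicate 3.

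The neighbours of each replaced gene were compared to ask whether a replacement changed expression beside it. None of the 19 tested neighbours passed the threshold in its own strain, in edgeR or in DESeq2 (0 each), and 1 had an unadjusted p under 0.05. That 1 was EFB1, a translation elongation factor gene beyond FUN14, at 536 ± 51.2 against 924 ± 308 CPM (−0.77 ± 0.31, edgeR adjusted p = 0.233, and 0.140 over its strain's neighbours). Beside GIP4, SNC1 stood at 188 ± 57.5 against 127 ± 84.8 CPM and POP5 at 157 ± 15.6 against 152 ± 96.6. Beside FUN26, CCR4 stood at 262 ± 57.4 against 187 ± 52.0 CPM and MAK16 at 289 ± 81.8 against 365 ± 140. Beside FUN14, ERP2 stood at 148 ± 53.7 against 94.5 ± 17.5 CPM and CYS3 at 1263 ± 191 against 1319 ± 280. The median absolute log2 fold change was 0.39 over 7 neighbours of GIP4, 0.39 over 5 of FUN26 and 0.10 over 6 of FUN14, and the share of genome runs at least as high was 0.236, 0.242 and 0.990. SEO1 lies near the chromosome end, and its 1 tested neighbour, GDH3, stood at 195 ± 65.1 against 228 ± 72.5 CPM. Without the count filter its 9 fitted neighbours had a median of 1.37, a share of 0.00456, but of these only GDH3 had enough counts to pass the filter. Within 10 ORF numbers its 4 tested neighbours had a median of 0.19 against wild-type (share 0.729) and of 0.70 against the other strains (share 0.00435). Of these, 0 were called in edgeR in either comparison and 0 had an unadjusted p under 0.05 against wild-type. Their log2 fold changes against wild-type ran from −0.20 to 0.48 in the SEO1 heterozygote and from −3.61 to −0.91 in the FUN14 heterozygote. All 4 were also lower in the FUN26 heterozygote and higher in the GIP4 heterozygote, and none passed the threshold in any strain. The share of 0.00435 therefore need not come from a change in the SEO1 heterozygote.

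**Figure D5:**
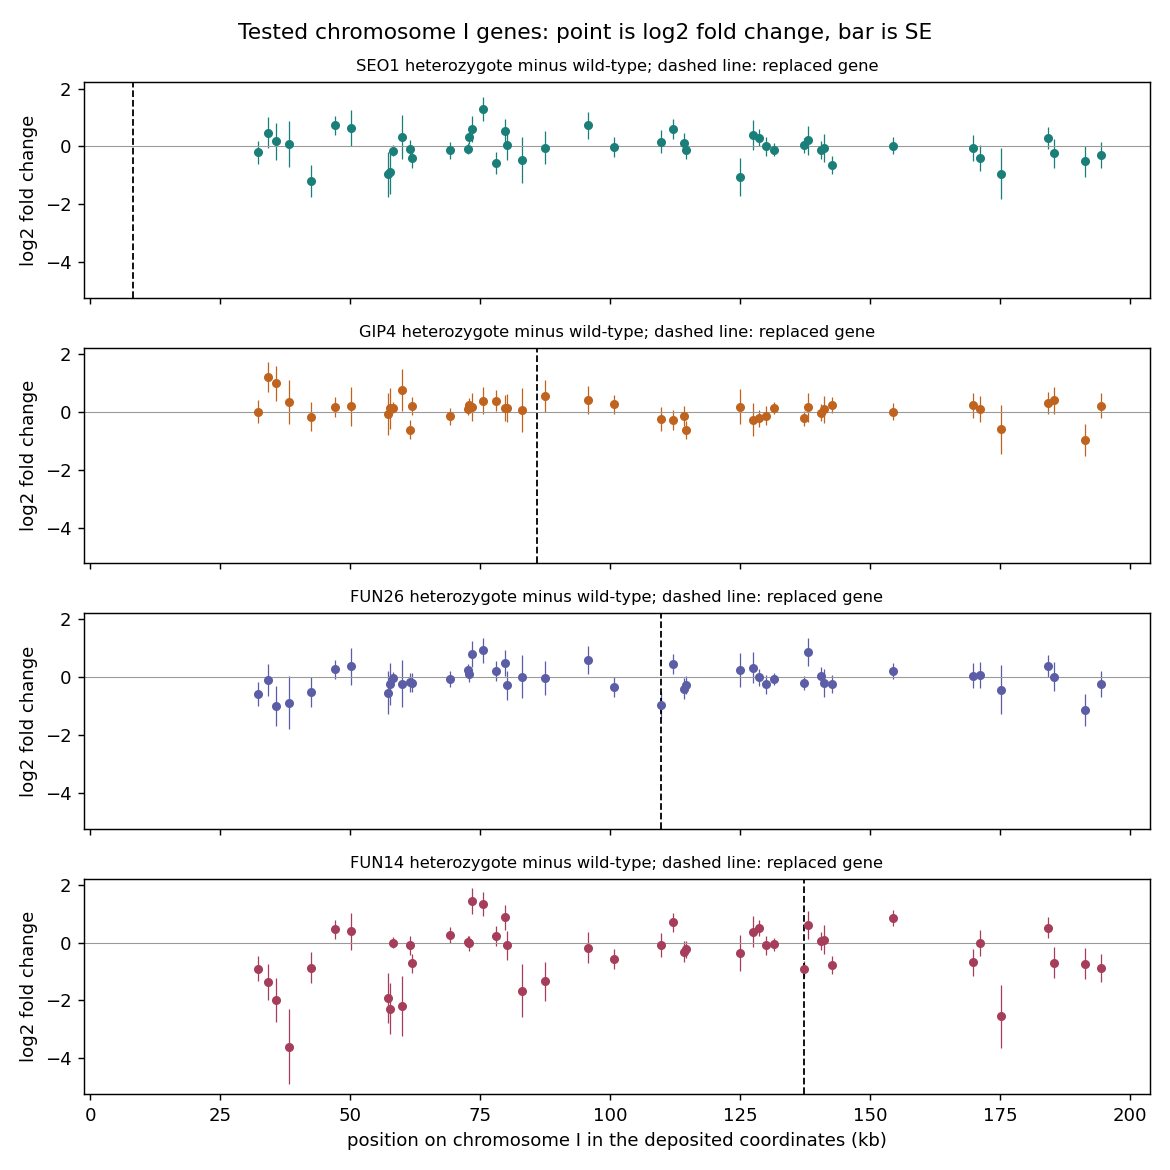
Log2 fold change against wild-type (points, with SE as bars) of the tested chromosome I genes along their deposited coordinates in kilobases, 1 panel per heterozygote, with the replaced gene as a dashed line. None of the 19 tested neighbours passed the threshold in its own strain.

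For the auxotrophic markers of the background no difference was detected between wild-type and strains. HIS3 stood at 573 ± 258 CPM in wild-type and 670 ± 122 in the strains (exact permutation p = 0.195), LYS2 at 23.5 ± 8.94 and 30.8 ± 12.7 (p = 0.320) and MET17 at 142 ± 27.0 and 135 ± 74.7 (p = 0.622), by the same exact permutation test. HIS3 was at 139 CPM in wild-type replicate 3 against 572 to 772 in the other wild-type libraries. MET17 had 0 counts in GIP4 replicate 1 and 2 in FUN26 replicate 2, while every other library had 6 to 26. LEU2 had 1 count each in wild-type replicates 5 and 6 and none elsewhere, and URA3 had no count in any library. Median expression per chromosome, for chromosomes with at least 20 tested genes, lay between −0.30 and 0.34 on the log2 scale around the mean of all libraries. Both ends were chromosome I in wild-type, in replicates 3 and 6, and in the strain libraries chromosome I ran from −0.18 to 0.22.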

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

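The tests in this part were chosen only after the result was seen, except the thinning to equal depth, the prediction from the library axis and the counts of other splits.

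The summed a-specific and haploid-specific genes were higher in every library labelled wild-type than in any strain library, although single genes such as STE4 in wild-type replicate 3 (49.0 CPM, against 65.2 in FUN26 replicate 3) were not. Alpha cells mixed into the wild-type libraries would raise alpha-specific genes too, but their summed CPM differed by a ratio of only 1.19. Much of that sum was MF(ALPHA)2, at 16.4 to 74.6 CPM in wild-type and 0 to 98.6 in the strains. Wild-type replicate 5 had a sum of 174 CPM, against 118 in the highest strain library. SAG1 stood at 69.7 and 32.8 CPM in wild-type replicates 5 and 6, against at most 17.4 in the strains. A small share of alpha cells in these libraries is therefore not excluded. Haploid BY4741 cells lack MET17, and MET17 had at least 7 counts in each of these libraries. Depth is argued against as well, since the lowest wild-type library held 5.49 times the a-specific CPM of the highest strain library while total counts overlapped. What stays open is that the cells labelled wild-type had lost the a/alpha state of a mating-incompetent diploid. Low mean IME4 (exact permutation p = 0.000808) is a weak further sign of that loss. For IME4 the wild-type libraries stood at 0 to 22.2 CPM, which is few counts each, and the lowest strain library lay within that range. Reads of IME4 and of its antisense transcript are also counted together. The loss of the a/alpha state is a hypothesis, found and tested on the same data.

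One axis separated libraries within groups and held 44.8% of the variance. It followed the GC slope of the libraries (r = −0.90, permutation p = 1.00e-05, adjusted p = 2.00e-05 over 2 relations; rho = −0.85, p = 4.00e-05; r = −0.88 without the 2 libraries farthest from the median slope). Score and GC slope were both computed from the same log2 CPM values, so this permutation test does not compare independent measures. Total count gave r = −0.49 (permutation p = 0.05, adjusted p = 0.05), rho = −0.50 (p = 0.04) and r = −0.68 without 2 libraries. A GC correction left 39.8% of the variance on the axis, so GC content was not the whole cause. Thinning to 52304 counts left 37.8% on an axis that correlated with the first at 0.999, so depth was not the whole cause either. The labels give no batch, and no biological explanation was tested.

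A set of chaperone genes (HSP104, HSP42, HSP78, SSA4 and APJ1), chosen by their values here, was higher in the FUN14 heterozygote. Over all genes only APJ1 passed the edgeR threshold against wild-type, the others being at adjusted p from 0.0819 to 0.143. Against the other strains none passed (adjusted p from 0.144 to 0.375). The library axis predicted a median share of 0.0743 of their log2 fold changes. These genes were picked by a test against the spread within groups, where the axis is strong. Genes that follow the axis were thus unlikely to be picked, so a low share was likely beforehand and does not decide whether the axis is the cause. The GC correction lowered their mean fold change by 8.48%, which argues against GC content as the whole cause. The APJ1 call nevertheless ended with the GC correction (1.82 ± 0.43, adjusted p = 0.0723, against 2.13 ± 0.44, adjusted p = 0.0343), since its estimate fell while its spread stayed, and it also ended with 1 surrogate variable (1.81 ± 0.48, adjusted p = 0.135), with only the groups compared (2.12, adjusted p = 0.0964), with wild-type replicates 4 to 6 alone (1.75) and without wild-type libraries 3 and 5 (2.18). Whether targets of the heat-shock factor rose together stays open. For 15 targets marked as not seen before the test, the median log2 difference from the other strains was 0.13 (95% interval 0.01 to 0.33). Camera gave p = 0.122, or 0.318 with an estimated correlation. The interval takes the genes as independent. Among the 15, HSP82 and HSP26 belong to the stress list and SSA1 to the FUN14 neighbours, which had been tested before. The stress-list members that had risen were left out, which can lower the median of this set. The camera result also depends on the choice of genes, because an earlier draft of the list that left out AHA1, HCH1 and HSP26 from these targets gave camera p = 0.0190, or 0.181 with an estimated correlation. The rule was also changed after this result was seen: as first written, these values would have counted against the explanation, and the upper bound of the interval is now asked to lie under 0.2 too.

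Within wild-type, 98 measures were checked for a single library far from the other 4, and 6 had one, where 4.90 are due to chance; 5 of the 6 were in wild-type replicate 3. Replicate 3 had a GC slope of −0.41 against 0.17 to 0.33 in the others, FAR1 at 294 CPM against 129 to 156, HIS5 at 147 against 75.2 to 89.6, NMD3 at 425 against 249 to 289, and CCC1 at 49.0 against 156 to 196. ADE5,7 was at 105 CPM in the mean of wild-type replicates 1 and 2 against 178 to 196. GIP4, FUN26 and FUN14 differed between their own strain and the other 3 strains, by log2 differences of −2.001, −0.90 and −0.77, as the design of the strains implies.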

How the results depend on the processing

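The settings tested only after the result was seen were wild-type replicates 1 and 2 as separate libraries, occupancy-corrected counts, no wild-type libraries 3 and 5, the GC correction, 1 surrogate variable, and the other strains as reference.

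DESeq2 called 34 genes in the FUN14 heterozygote, 17 in the mean of the strains and 2 among the strains, with FUN26 at −0.98 (p = 0.0503 beside the exact p of 0.125). FUN26 also missed 0.05 with upper-quartile scaling (−0.89), total counts (−0.89), library sizes without chromosome I and the top 20 genes (−0.89) and the GC correction (−0.86). Without a filter, 8 genes were called in the SEO1 heterozygote and 22 in the mean, FUN26 was at −0.96, and the SEO1 neighbours had a median of 1.37; with a mean of at least 10 CPM, 8, 22 and −0.96. With only the groups compared, 2 genes were called in the SEO1 and 4 in the FUN14 heterozygote and 1 among strains, and FUN26 was at −0.91. With wild-type replicates 1 to 3, the GIP4 and FUN26 heterozygotes had 2 genes each, FUN26 was at −0.69, and FUN14 had 12 (9 higher, 3 lower); with replicates 4 to 6, GIP4 had 4, FUN14 had 14 (0 higher in edgeR, against 2 of 9 with all), 1 differed among strains, and the stress list in the SEO1 heterozygote was lower relative to other genes, though its median stayed positive at 0.12 (adjusted p = 0.718 in camera).

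Libraries with the same replicate number correlated more often than others but not throughout: from −0.48 to 0.51 with a median of 0.23 and 20 of 30 pairs over 0.1, against −0.63 to 0.59, a median of −0.06 and 25 of 96 for different numbers. Of 15 libraries 7 correlated best with their own number, a hint from the data and not the design, so the replicate block was not taken as a paired test. It gave 15, 20, 22 and 148 genes in the SEO1, GIP4, FUN26 and FUN14 heterozygotes (9, 12, 15 and 50 higher). In the mean it gave 52 (33 higher and 19 lower, against 1 and 10 in the main fit), and among strains 2. More than the block differed from the main fit, since wild-type replicates 1 and 2 counted as separate libraries. Replicate numbers found only in wild-type held a single library each and were fitted exactly. The block contrasts with wild-type thus rested on its replicates 1 to 3. With wild-type replicates 1 and 2 separate, 8 and 23 genes were called in the SEO1 and FUN14 heterozygotes; without wild-type libraries 3 and 5, 4 in GIP4, 15 in FUN14 and 1 among strains. With 1 surrogate variable, 11 genes were called in the SEO1 heterozygote, and the ribosomal protein list in the FUN14 heterozygote was lower relative to other genes, with a positive median of 0.00349 (adjusted p = 0.976 in camera). With an estimated correlation 13 of 27 lists passed.

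Leaving out each library gave 2 to 114 genes in the SEO1, 4 to 11 in the GIP4, 1 to 7 in the FUN26 and 2 to 175 in the FUN14 heterozygote, 8 to 16 in the mean, 0 to 217 among strains and 22 to 31 lists. GIP4 ranged from −2.68 to −1.71, FUN26 from −1.47 to −0.68 and FUN14 from −1.01 to −0.77. Neighbour medians ranged from 0.03 to 0.56 for SEO1, 0.16 to 0.41 for GIP4, 0.19 to 0.60 for FUN26 and 0.09 to 0.21 for FUN14. For single genes and lists, the other settings left 2283 values on the same side of their threshold. With an unchanged sign, 44 passed it only in the alternative and 99 only in the main fit. A further 2 changed sign with a pass in at least 1 fit (the lists named above). Leaving out a library gave 2691, 32, 110 and 0 in these classes. A change of sign without a pass in either fit counts among the values on the same side.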

Other observations

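All tests in this part were fixed before the results were seen, apart from the values for MET17 and IME4, which come from tests chosen afterwards.

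Other splits of the same libraries were counted for each edgeR comparison. In the GIP4 heterozygote the real split called 8 genes and the highest other split 1, and only 1 of 56 splits, the real one, reached 8. In the FUN26 heterozygote the real split called 6, the highest other 3, and 1 of 56 reached 6. Chance can be excluded at 0.05 for both, without adjustment over the comparisons. In the mean of the strains the real split called 11, and 4 of 100 splits, the real one included, reached that number, the highest other calling 859. That share lies under 0.05, the limit fixed beforehand. It comes from a random draw of 100 splits and was not adjusted over the comparisons, so chance is not firmly excluded there. In the SEO1 heterozygote 3 of 56 splits reached the real 4, the highest other calling 707, and in the FUN14 heterozygote 3 of 56 reached the real 9, the highest other calling 99, so chance cannot be excluded for these counts. Among the strains the real count was 0, which each of the 100 splits reaches by construction, so that count decides nothing; the highest other split called 366.

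The splits that called many times the real count point to a structure of the libraries other than the groups. The split with 707 genes put wild-type replicate 3 with SEO1 replicates 2 and 3, and the split with 859 put these libraries with FUN14 replicates 2 and 3, all of them on the positive side of the library axis.

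IME4, an RNA methyltransferase gene needed for meiosis, stood at 13.7 ± 8.97 CPM in wild-type and 98.0 ± 60.3 in the strains. The lowest strain library lay within the wild-type range. MET17 had 0 counts in GIP4 replicate 1, where the other 2 libraries of that strain had 13 and 15.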
